A study of Sus scrofa with 90 samples.

How the data were processed

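RNA from the Longissimus dorsi muscle of 10 piglets was measured by hybridisation to nylon cDNA arrays. Propylene glycol is a solvent used as a vehicle for injected drugs. Each piglet received it by intramuscular injection at different times, so that lesions of 6 h, 2 d, 7 d and 21 d could be collected together with a site that was not injected. The labels name 90 columns for 48 muscle samples from the pigs C to L. There were 10 control samples, 10 lesions of 6 h, 10 lesions of 2 d, 9 lesions of 7 d (none listed for pig J) and 9 lesions of 21 d (none listed for pig L).

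Per the labels, cDNA carrying a radioactive label was hybridised to 1 array per sample, the array was read from an imaging plate at a resolution of 25 micrometres, and spots were quantified with a grid of fixed diameter. The deposited values are on a log scale whose base is not given in the sources used here, a unit other than counts or intensities. They ran from -1.33 to 5.00. A base of 10 would need more than 5 decades between features, so base 2 and the natural logarithm stay possible. A difference of 1 log unit is a 2-fold difference in base 2 and a 2.72-fold difference on the natural scale. How the authors made the log values, centred them and chose the features with values is not given in the sources used here.

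The table lists 4608 features, of which 1908 had a value in every column and were tested. A further 2695 had no value in any column, and 5 had values in 2 or 3 columns only. Of the tested features 206 carry 1 gene symbol, for 121 genes, and 1702 carry none. The gene identifiers of 204 of the 206 matched the current gene table. Each array carries its features in duplicate, and both duplicates were listed as columns for 42 samples and 1 of them for 6 samples. The columns held identical values in 41 of the 42 pairs, so they are not independent measurements, and they were averaged before the test. The pair that differed belonged to the 6 h lesion of pig J, where 1 column was an exact copy of the control of pig I. That column was left out, a departure decided on seeing the copy. The copied values had an SD over features of 1.16, against at most 0.903 in the 6 h lesions. Their feature listed as XIRP2 was at -0.025, against 1.16 ± 0.19 (SD, n = 10) at 6 h. These values argue against the label of a 6 h lesion for them, while it cannot be shown from which pig they came.

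The animal was a fixed block, because the study placed a lesion of each age and a control in every pig, at randomised sites. As a check of the pairing, deviations from the group means were correlated between samples. The median correlation was -0.0267 between samples of the same animal and -0.0229 between samples of different animals, so the pairing rests on the design and not on the values. The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule for scaling was fixed as well. Quantile normalization was to be used if array medians ranged over more than 0.1, and they ranged over 0.112 (from 0.0120 to 0.124). The quantile-normalized values were fitted by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with terms for group and animal over all 5 groups. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the 1908 features within each comparison, and a feature was called at an adjusted p below 0.05. Figures were drawn with matplotlib 3.10.9, and feature orders were searched with numpy 2.4.6. Arrays carry no count of molecules, so the number of arrays limits the precision.

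The genes named were, for each lesion age against control, up to 8 with the largest rise and up to 8 with the largest fall among those called with the same sign in at least 80% of the animals, using 1 feature per gene (the one with the highest mean). From each list with at least 5 measured genes, the 3 members with the smallest adjusted p were also eligible. For the steps between ages the rule took the 4 largest rises and falls. Genes outside the rule are marked as chosen after their values were seen. Of 40 lists, 7 had at least 5 measured genes and were tested by camera in limma, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 28 tests. They are slow fibre sarcomere, fast fibre sarcomere, shared sarcomere and Z disc, glycolysis and glycogen, nuclear encoded oxidative phosphorylation, ribosomal proteins, and non-muscle cytoskeleton. A further 20 lists had 1 to 4 measured genes and were not tested. No measured feature carried a symbol from the other 13 lists, among them the markers of neutrophils, macrophages, lymphocytes and fibroblasts, the collagens, and the haemoglobins.

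The fit was tested on simulated data in which 200 of 1908 features were changed. Of changes of 0.3, it recovered 48% at 6 h, 35% at 2 d, 45% at 7 d and 35% at 21 d. Of changes of 0.6, it recovered 92%, 85%, 88% and 88%. False calls numbered 1, 1, 7 and 0. Each age had a single simulated data set, so the shares are not compared between ages. Recovery where few features change, as at 2 d, was not simulated. To account for the control samples that all lesion ages share, 100 simulations without any change gave the correlation between ages that sharing alone produces.

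The alternatives fixed beforehand were no animal block, the animal as a random block, the table values without quantile normalization, arrays centred on their median, leaving out the 25% dimmest features, the first column of each array only, leaving out samples with 1 column, array weights, a trend and robust prior, only the groups compared in the fit, the array number as a covariate, and leaving out each animal. Background correction was planned only for linear values and was not run. Alternatives chosen after seeing the data were arrays scaled to equal mean and SD, leaving out the 6 h array of pig F, 3 treatments of the copied column, subtraction of local trends on the membrane, and the SD of each array as a covariate.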

Results

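The study followed pig muscle after an intramuscular injection of propylene glycol, to describe how gene expression in the lesion changes with its age. Expression was measured on 48 arrays from 10 pigs, with 10 controls, 10 lesions of 6 h, 10 of 2 d, 9 of 7 d and 9 of 21 d. Each array gave a value for 1908 tested features, of which 206 carry a gene symbol. Differences are lesion minus control in log units, with the standard error (SE) of the fit. Each adjusted p comes from limma, and the count of animals gives those whose own difference had the same sign.

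Several measured facts bear on all comparisons. The 6 h array of pig F was out of register with the feature list. Its values correlated with the mean of the other arrays at r = 0.240 in place and at r = 0.739 when moved by 384 features, over 910 features. The other 47 arrays had r of at least 0.718 in place and at most 0.346 at any other shift tried. This array was kept as planned, and counts of called features and genes without it are given below. The counts of animals at 6 h include this array, though its values appear to stand under other features than their own. The SD of the values within an array averaged 0.976 ± 0.237 (SD, n = 10) in controls, 0.719 ± 0.116 (n = 10) at 6 h, 0.805 ± 0.0985 (n = 10) at 2 d, 0.607 ± 0.158 (n = 9) at 7 d and 0.643 ± 0.196 (n = 9) at 21 d.

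**Figure D1:**
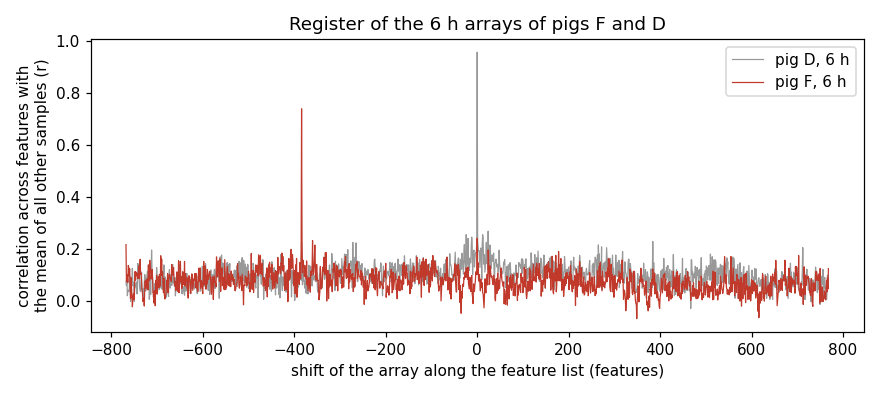
Correlation across features (r, vertical axis) between 1 array and the mean of all other samples at each shift of the array along the feature list (horizontal axis, in features), for the 6 h lesions of pig F and pig D. The array of pig F reaches 0.739 at a shift of 384 features against 0.240 in place, and that of pig D is highest in place.

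Features with the same symbol were not shown to move together beyond chance. The median correlation of their normalized values across arrays, with the 6 h array of pig F left out, was 0.0253. It was -0.00616 with symbols permuted (347 pairs, 10000 permutations, one-sided permutation p = 0.075). Genes abundant in muscle (fast fibre, glycolysis and creatine kinase) had values for 37.8% of their 201 listed features, against 41.6% of the other features (two-sided Fisher exact p = 0.306). Whether each symbol belongs to its feature is undecided, and a gene named below stands for the feature listed under that symbol.

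At 6 h the clearest rise was in the feature listed as XIRP2, a protein that binds actin at the ends and junctions of myofibrils. It stood at -0.004 ± 0.14 (SD, n = 10) in controls and rose by 1.16 (SE 0.113, adjusted p = 2.31e-09) in 10 of 10 animals. JAK1, a tyrosine kinase of cytokine receptors, rose by 0.59 (SE 0.119, adjusted p = 0.00113, 9 of 10 animals). MYH7, the slow myosin heavy chain, rose by 0.46 (SE 0.108, adjusted p = 0.00453, 9 of 10 animals) in the feature with the highest mean, while another of its 4 features fell at 6 h and 7 d. TPM2, beta-tropomyosin, had the largest fall among the genes with a symbol that were called, at -0.61 (SE 0.109, adjusted p = 0.000239, 10 of 10 animals). Each count of animals includes the array of pig F that was out of register. Without that array XIRP2 was at 1.21, JAK1 at 0.68, MYH7 at 0.36 and TPM2 at -0.56, all still called.

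Of the 121 genes with a symbol, 10 changed at 6 h, 3 upwards and 7 downwards. There were 12 without the 6 h array of pig F, 6 upwards and 6 downwards, with HSPE1, NPPA and UGP2 added as rises and TPI1 lost. HSPE1, read after its values were seen, was then at 0.66 (SE 0.0886, adjusted p = 1.071e-06 by limma). With that array it was at 0.43 (adjusted p = 0.0721). Its adjusted p without that array was smaller than that of JAK1 (2.864e-05). The other falls were in MAPK12, a p38 kinase of muscle, at -0.49 (adjusted p = 0.03), MIF, a cytokine, at -0.44 (adjusted p = 0.0261), HTT, huntingtin, at -0.43 (adjusted p = 0.0134), the glycolytic enzyme TPI1 at -0.34 (adjusted p = 0.0394), QDPR, which regenerates tetrahydrobiopterin, at -0.29 (adjusted p = 0.0161), and the muscle creatine kinase CKM at -0.27 (adjusted p = 0.0149). The difference had the same sign in 10 of 10 animals for MAPK12 and HTT and in 8 of 10 for the others, with the 6 h array of pig F counted. The features of MIF and HTT lie 1 place apart on the feature list. Over all features, 210 were called at 6 h, 91 higher and 119 lower, and 508 had an unadjusted p below 0.05. Without the 6 h array of pig F the count was 225, with 132 higher and 93 lower, and 162 features were called both ways. With the 6 h lesion of pig J and the control of pig I left out, which share copied values, it was 144 (66 higher, 78 lower). On table values without quantile normalization it was 535 (109 higher, 426 lower), and with array SD in the model 104 (89 higher, 15 lower). With array SD in the model XIRP2, JAK1 and TPM2 stayed called, while MYH7 at 0.32 (SE 0.117, adjusted p = 0.108) and the other 6 falls did not. QDPR stayed at -0.28 while its SE grew from 0.0802 to 0.0929 (adjusted p = 0.0688). The others shrank, to -0.34 for MAPK12, -0.26 for MIF, -0.22 for HTT, -0.24 for TPI1 and -0.22 for CKM (adjusted p from 0.14 to 0.307). MYH7 was also not called on table values. Subtracting the local trend ended the calls of MAPK12 at -0.45, MIF at -0.34, TPI1 at -0.25, QDPR at -0.18 and CKM at -0.19 (adjusted p from 0.0679 to 0.15). Leaving out 1 pig ended the call of MAPK12 (pig E, G or H; adjusted p up to 0.0684), MIF (F, G, I, K or L; up to 0.0816), TPI1 (C, E, F, G, H, I or K; up to 0.10) and QDPR (G; 0.0568). Without the 6 h array of pig F alone, TPI1 at 6 h was at -0.22 (adjusted p = 0.086), and MAPK12 at 6 h shrank to -0.27 and stayed called (adjusted p = 0.0178). The call of TPI1 at 6 h also needs the animal as a fixed block, with an adjusted p of 0.0641 without the block and 0.0746 with the animal as a random block.

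**Figure D2:**
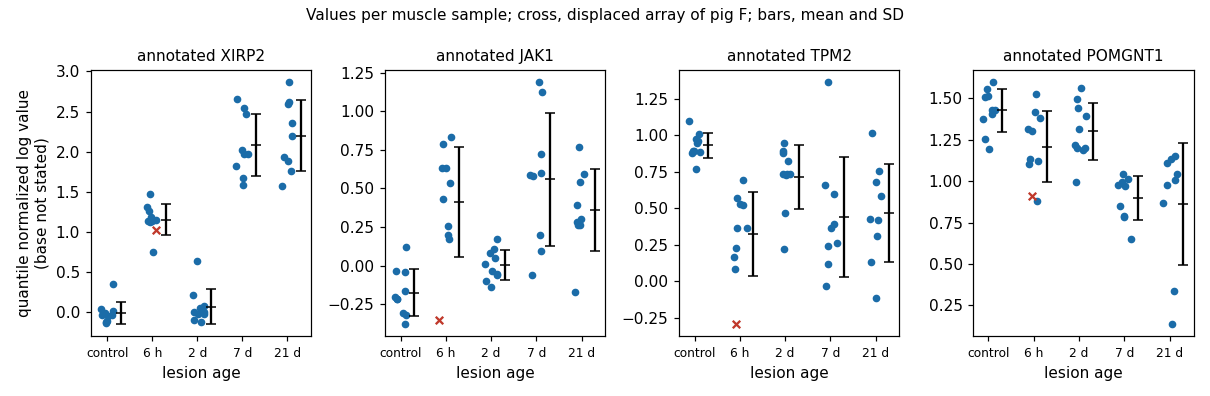
Quantile-normalized values (log units) of the features listed as XIRP2, JAK1, TPM2 and POMGNT1, with each sample as a point by group, bars for the mean and SD, and the 6 h array of pig F as a cross. XIRP2 averages -0.004 in controls and 2.20 at 21 d.

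At 2 d few features differed from control, and no gene with a symbol passed the test. The XIRP2 feature differed by 0.08 (SE 0.113, adjusted p = 0.866, 6 of 10 animals with that sign). JAK1 differed by 0.18 (SE 0.119, adjusted p = 0.765), TPM2 by -0.21 (SE 0.109, adjusted p = 0.721) and MYH7 by 0.25 (SE 0.108, adjusted p = 0.57). By limma, 0 of 121 genes were called, and 6 had an unadjusted p below 0.05.

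Over all features, 10 rose and 0 fell at 2 d by limma, with 138 at an unadjusted p below 0.05, of which 60 were lower. None of the 10 carries a symbol. The one with the smallest p, feature 7571, was chosen after its values were seen. It rose by 0.97 (SE 0.0885, adjusted p = 3.874e-10), and it was also higher at 6 h by 0.37 (adjusted p = 0.00566) and at 7 d by 0.35 (adjusted p = 0.00522). Of the 10 features, 5 were also called higher at 6 h, 6 at 7 d and 3 at 21 d. The count was 55 with array weights (37 higher, 18 lower), 32 on median-centred values (22 higher, 10 lower), 23 on table values (16 higher, 7 lower), 22 with only controls and 2 d lesions in the fit, and 14 without the 6 h array of pig F.

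At 7 d the XIRP2 feature rose by 2.07 (SE 0.117, adjusted p = 6.318e-17, 9 of 9 animals). JAK1 rose by 0.73 (SE 0.123, adjusted p = 2.857e-05, 8 of 9 animals). ANPEP, aminopeptidase N of the cell surface, rose by 0.64 (SE 0.122, adjusted p = 0.000182, 8 of 9 animals). UGP2, which makes UDP-glucose for glycogen, rose by 0.68 (SE 0.159, adjusted p = 0.00178, 9 of 9 animals). POMGNT1, an enzyme that glycosylates dystroglycan, fell by 0.53 (SE 0.104, adjusted p = 0.000243, 9 of 9 animals), and CKM fell by 0.37 (SE 0.0779, adjusted p = 0.000586, 9 of 9 animals).

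Of the 121 genes, 20 changed at 7 d, 8 upwards and 12 downwards, and 17 met the sign rule. All 20 stayed without the 6 h array of pig F, and 5 more were called (25, with 9 upwards and 16 downwards). Of the other rises, those that met the sign rule were HSPE1, a mitochondrial chaperonin, at 0.59 (adjusted p = 0.00933), MYH7 at 0.46 (adjusted p = 0.00228) and NPPA, a natriuretic peptide precursor, at 0.35 (adjusted p = 0.013). HSPE1 did so in 9 of 9 animals and MYH7 and NPPA in 8 of 9. Of the falls, the largest was in CAPNS1, the small calpain subunit, at -0.74 (SE 0.215, adjusted p = 0.011, 8 of 9 animals), with TPM2 at -0.46 (adjusted p = 0.00264), TPT1 at -0.43 (adjusted p = 0.000567), TPI1 at -0.39 (adjusted p = 0.0113), HTT at -0.38 (adjusted p = 0.0203) and QDPR at -0.38 (adjusted p = 0.000858). TPT1 and TPI1 fell in 9 of 9 animals, and TPM2, HTT and QDPR in 8 of 9. On table values HSPE1 at 7 d turned to -0.41 and MYH7 at 7 d to -0.0073, neither past the test, and UGP2 was not called (adjusted p = 0.0643). With array SD in the model the calls of MYH7, NPPA, CAPNS1, TPM2, TPI1 and HTT ended (adjusted p from 0.0854 to 0.724), through smaller differences and larger SEs. MYH7 went to 0.27 (SE 0.132), NPPA to 0.20 (SE 0.125), CAPNS1 to -0.53 (SE 0.268), TPM2 to -0.37 (SE 0.141), TPI1 to -0.25 (SE 0.141) and HTT to -0.09 (SE 0.132). Subtracting the local trend took TPT1 at 7 d to -0.19 (SE 0.0735, adjusted p = 0.0653), TPM2 at 7 d to -0.35 (adjusted p = 0.0507) and TPI1 at 7 d to -0.29 (adjusted p = 0.0758), which ended these calls. Leaving out 1 pig ended the call of CAPNS1 (pig G; adjusted p = 0.0616), NPPA (D, 0.0514, or I, 0.0562) and HTT (D, 0.0536, or E, 0.0972).

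Over all features, 393 were called at 7 d, 178 higher and 215 lower, and 591 had an unadjusted p below 0.05. The count was 484 without the 6 h array of pig F (205 higher, 279 lower). On table values 234 were higher and 478 lower, and the count was 198 with array SD in the model (152 higher, 46 lower).

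At 21 d the XIRP2 feature was higher than control by 2.21 (SE 0.117, adjusted p = 4.298e-18) and ANPEP by 1.11 (SE 0.122, adjusted p = 8.143e-09), each in 9 of 9 animals. JAK1 rose by 0.54 (SE 0.123, adjusted p = 0.00259, 9 of 9 animals). POMGNT1 fell by 0.55 (SE 0.104, adjusted p = 0.000254, 9 of 9 animals) and TPM2 fell by 0.47 (SE 0.112, adjusted p = 0.00485, 8 of 9 animals). These features were thus still apart from control at the oldest lesion.

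Of the 121 genes, 10 changed at 21 d, 6 upwards and 4 downwards, and 8 met the sign rule. All 10 stayed without the 6 h array of pig F, and 7 more were called (17, with 8 upwards and 9 downwards). MYH7 rose by 0.36 (adjusted p = 0.0305, 9 of 9 animals), NPPA rose by 0.35 (adjusted p = 0.0241, 8 of 9 animals) and QDPR fell by 0.33 (adjusted p = 0.00663, 8 of 9 animals). UGP2 at 0.49 and CKM at -0.24 (adjusted p = 0.0425 each) passed the test without meeting the sign rule. UGP2 is named as a list member, and CKM was chosen after its values were seen. MYH7 turned to -0.072 on table values, not past the test. With array SD in the model MYH7, NPPA, TPM2, QDPR and UGP2 were no longer called (adjusted p = 0.544, 0.426, 0.118, 0.0608 and 0.0511). MYH7 shrank to 0.18, NPPA to 0.21 and TPM2 to -0.38. QDPR stayed at -0.32 and UGP2 grew to 0.63, and their calls ended because the SE grew, from 0.0829 to 0.104 and from 0.159 to 0.196. Subtracting the local trend ended the calls of QDPR at -0.24, UGP2 at 0.37 and CKM at -0.19 (adjusted p = 0.061, 0.219 and 0.15). Leaving out 1 pig ended the call of MYH7 (pig D, E, J or K; adjusted p up to 0.123), NPPA (D, I or J; up to 0.107), QDPR (I; 0.0516) and UGP2 (D, E, G, H, K or L; up to 0.142).

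Over all features, 177 were called at 21 d, 91 higher and 86 lower, and 450 had an unadjusted p below 0.05. The count was 281 without the 6 h array of pig F (124 higher, 157 lower) and 110 without pig I (77 higher, 33 lower). With the 6 h lesion of pig J and the control of pig I left out it was 121 (76 higher, 45 lower). It was 683 on table values (168 higher, 515 lower) and 97 with array SD in the model (87 higher, 10 lower).

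**Figure D3:**
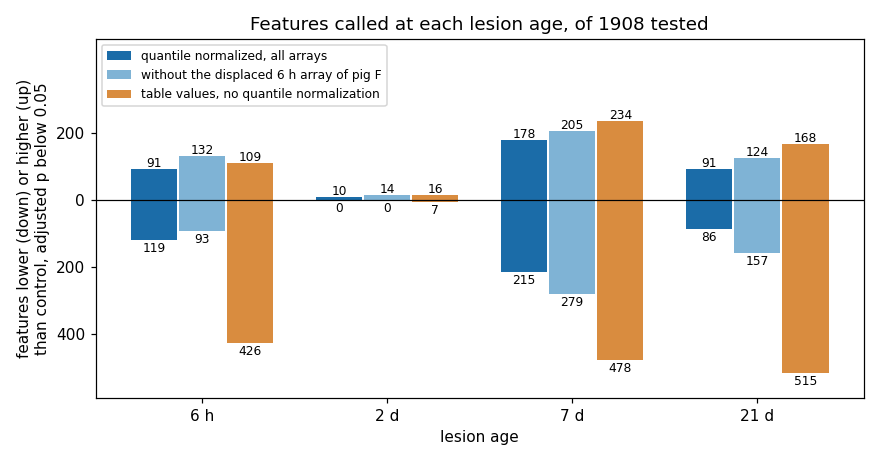
Number of features called higher (up) or lower (down) than control at each lesion age, of 1908 tested, with quantile normalization, without the 6 h array of pig F, and on table values. The 2 d lesions have 10, 14 and 23 called features, and the falls at 6 h, 7 d and 21 d are more numerous on table values.

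Between 6 h and 2 d the XIRP2 feature returned towards its control level, with a difference of -1.08 (SE 0.113, adjusted p = 1.676e-08). JAK1 was lower at 2 d than at 6 h by -0.41 (SE 0.119, adjusted p = 0.0368), and TPM2 was higher by 0.39 (SE 0.109, adjusted p = 0.0245). These were the 3 genes with a symbol that differed. Over all features 88 differed, 31 higher and 57 lower at 2 d, with 364 at an unadjusted p below 0.05. The count was 118 without the 6 h array of pig F (29 higher, 89 lower), with 5 genes with a symbol, and 37 on table values. Leaving out 1 pig ended the call of TPM2 (pig F, H, K or L; adjusted p up to 0.106) and of JAK1 (C, D, E, G, I, J, K or L; up to 0.128), and neither was called on table values. The call of TPM2 at 2 d against 6 h was also lost without the animal block (adjusted p = 0.0544) and with the animal as a random block (adjusted p = 0.067), and that of JAK1 at 2 d against 6 h with the random block (adjusted p = 0.0535). Subtracting the local trend ended both calls, with TPM2 at 2 d against 6 h at 0.32 (adjusted p = 0.145) and JAK1 at 2 d against 6 h at -0.39 (adjusted p = 0.0808).

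Between 2 d and 7 d XIRP2 and JAK1 rose again. XIRP2 was higher at 7 d by 1.99 (SE 0.117, adjusted p = 2.427e-16), JAK1 by 0.55 (SE 0.123, adjusted p = 0.00175), ANPEP by 0.45 (SE 0.122, adjusted p = 0.0104) and RACK1, a scaffold protein of the ribosome, by 0.38 (SE 0.104, adjusted p = 0.0104). CAPNS1 was lower by -0.65 (SE 0.215, adjusted p = 0.04), POMGNT1 by -0.41 (SE 0.104, adjusted p = 0.00629), TPT1 by -0.36 (SE 0.09, adjusted p = 0.00555) and COX7A1, a subunit of cytochrome oxidase, by -0.31 (SE 0.103, adjusted p = 0.0372). In all, 11 genes with a symbol differed, 5 higher and 6 lower. Over all features 235 differed, 146 higher and 89 lower at 7 d, with 450 at an unadjusted p below 0.05. The count was 314 without the 6 h array of pig F (180 higher, 134 lower), with 16 genes with a symbol. It was 143 without pig E and 117 on median-centred values, where the balance turned (52 higher, 65 lower). It was 89 on table values (41 higher, 48 lower), where of these 8 genes XIRP2 and POMGNT1 alone stayed called. Leaving out 1 pig ended the call of ANPEP (pig E; adjusted p = 0.0667), CAPNS1 (D, E, G, H, I, J, K or L; up to 0.164) and COX7A1 (C, D, E, F, J, K or L; up to 0.178). Subtracting the local trend ended those of CAPNS1 at 7 d against 2 d at -0.62 (adjusted p = 0.065) and TPT1 at 7 d against 2 d at -0.18 (adjusted p = 0.0879). With array SD in the model CAPNS1 at 7 d against 2 d was at -0.54 (SE 0.229, adjusted p = 0.126) and COX7A1 at 7 d against 2 d stayed at -0.31 with a larger SE (0.111, adjusted p = 0.0593), neither called.

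Between 7 d and 21 d no gene with a symbol differed by limma (0 of 121, with 7 at an unadjusted p below 0.05). Over all features 5 differed, 3 higher and 2 lower at 21 d, with 109 at an unadjusted p below 0.05, and none of the 5 carries a symbol. The count was 13 without the 6 h array of pig F (3 higher, 10 lower). Leaving out 1 pig gave 3 (pig D, G or J), 9 (F), 2 (I) or 1 (H or K). On table values it was 0 by limma, with 14 at an unadjusted p below 0.05.

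Across the time course, 342 features differed from control by limma's moderated F test over the 4 lesion ages, and 432 without the 6 h array of pig F. The count was 638 on median-centred values and 207 with array SD in the model. The lesions of 6 h, 7 d and 21 d had 47 features in common that were higher than control and 38 that were lower. These were picked by their differences at 6 h, 7 d and 21 d, which favours a contrast with 2 d. By the direct test, 29 of the 47 were higher at 6 h than at 2 d and 43 were higher at 7 d than at 2 d. Of the 38, 7 were lower at 6 h than at 2 d and 19 lower at 7 d. At 2 d 40 of the 47 still lay above control (median difference 0.083) and 36 of the 38 below it (median -0.188). The controls shared by all ages favour this too. The features in common were 70 and 54 without the 6 h array of pig F. Of the 70, 48 were higher at 6 h than at 2 d and 62 at 7 d, and of the 54, 10 were lower at 6 h and 30 at 7 d. No feature was called in opposite directions at different ages by limma (0, and 0 at an unadjusted p below 0.05).

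Across features, which are not independent replicates, differences at 7 d and 21 d correlated at r = 0.891, against 0.469 from shared controls alone in 100 simulations and 0.796 with the controls divided between the ages. For 6 h and 7 d r was 0.802, against 0.475 and 0.706, and for 6 h and 21 d it was 0.735, against 0.478 and 0.622. The 2 d differences correlated with those at 6 h, 7 d and 21 d at 0.486, 0.481 and 0.445, against 0.487, 0.485 and 0.461 from shared controls alone. With the controls divided these were 0.314, 0.337 and 0.289. The covariances were 0.0167, 0.0219 and 0.0171, against means of 0.00777, 0.00815 and 0.00789 from shared controls alone, so a change at 2 d in common with the other ages is not excluded. At 7 d and 21 d together 80 features were called higher and 73 lower.

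In the lists of genes single members were called, and no list passed the test as a whole. Whether the symbols belong to their features is undecided, so this does not show that no list moved. By camera 0 of 28 tests passed, and 3 had an unadjusted p below 0.05. Those 3 were the shared sarcomere and Z disc list at 6 h, 7 d and 21 d, upwards, with an adjusted p of 0.0638 each and an adjusted p of 0.0771 with an estimated correlation. Its 5 measured genes are DES, FHL1, FHL3, SMPX and XIRP2, of which XIRP2 rose at each of these ages. Adjusted over the list alone, 2 rose at 6 h (XIRP2 and FHL1), 1 at 7 d and 1 at 21 d. Without pig D all 3 tests passed, with an adjusted p of 0.0426.

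Each gene of a list is read by its feature with the highest mean. Among 5 slow fibre genes, MYH7 by this feature rose at 6 h, 7 d and 21 d, though another of its features fell at 6 h and 7 d. Adjusted over the list alone, 1 rose at each of these ages, and 1 more fell at 21 d. That was TPM3, which without the 6 h array of pig F was called over all features (-0.35, adjusted p = 0.0135). At 7 d the test of this list pointed upwards while the median difference was -0.17 and the mean -0.01. Among 10 fast fibre genes, which by the list include TPM2, TPM2 fell at these ages, the same count adjusted over the list alone. Its test at 7 d pointed downwards, with a median of 0.0009 and a mean of -0.09. Of 9 genes of glycolysis and glycogen, TPI1 fell at 6 h and 7 d, and UGP2 rose at 7 d and 21 d. The tally at 6 h turned without the 6 h array of pig F, from 0 higher and 1 lower to 1 higher and 0 lower, since TPI1 was lost and UGP2 was called at 0.43 (adjusted p = 0.0299). Adjusted over the list alone, 2 fell at 6 h, 1 rose and 1 fell at 7 d, and 1 rose at 21 d. The test of that list at 21 d pointed upwards against a median of -0.08 and a mean of -0.05, and at 2 d it pointed upwards with a median of 0.06 and a mean of -0.0046.

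Of 5 genes of oxidative phosphorylation, COX7A1 fell at 7 d by 0.36 (SE 0.103, adjusted p = 0.00986), and this count was the same adjusted over the list alone. Its call was lost without pig E (adjusted p = 0.0509) and with array SD in the model (adjusted p = 0.0729), where it stayed at -0.36 while the SE grew from 0.103 to 0.13. Of 6 genes of the non-muscle cytoskeleton, TUBA1B, an alpha-tubulin, fell at 7 d by 0.23 (adjusted p = 0.0106). It was not called on table values, and TUBA1B at 7 d was at -0.07 (adjusted p = 0.598) with the local trend subtracted. Adjusted over the list alone, 1 fell at 7 d, and 1 rose and 1 fell at 21 d. Without the 6 h array of pig F these were called over all features at 21 d, ACTB at 0.35 (adjusted p = 0.0482) and TPM3, which is also in this list. By the feature with the highest mean, none of 12 ribosomal protein genes was called by limma at any age, over all features or adjusted over the list alone. Their unadjusted p was below 0.05 for 1 gene at 6 h, 0 at 2 d, 2 at 7 d and 0 at 21 d. Without the 6 h array of pig F, 1 of them, RPL10A, was called lower at 7 d. At 2 d no member of the 7 lists was called by limma, over all features or adjusted over the list alone, and 1 had an unadjusted p below 0.05 (MYH7).

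Some genes have several features, which did not always move alike. Of 10 CKM features, 2 were lower at 6 h, 4 at 7 d and 4 at 21 d, and none was called higher. Feature 5503 of MYH7 is the one that rose, while feature 4799 of the same symbol fell by 0.47 at 6 h (adjusted p = 0.00873) and by 0.58 at 7 d (adjusted p = 0.000598). Features listed as MYLPF, a fast myosin light chain, were also called in both directions at 6 h, 7 d and 21 d, chosen after their values were seen. Of 67 other features of the 51 list genes, 15 features of 9 genes were called at some age, and those named next were read after their values were seen. Feature 5922 of ENO3 fell at 6 h, 7 d and 21 d (by 0.45, 0.46 and 0.38), and feature 7526 of PFKM rose by 0.27 at 6 h and at 7 d, so the glycolysis tally rests on the feature taken. Another feature also fell for TNNC2 and RPL11 at 6 h, 7 d and 21 d and for RPS20 at 6 h, and another rose for MYOZ1 at 6 h and ACTB at 7 d. That MYOZ1 feature, 7646, lies 1 place from the XIRP2 feature, which rose by 1.16 at 6 h, and their deviations correlated at 0.557. The ANPEP feature lies 24 places from feature 5139, which rose by 2.45 at 7 d and 2.76 at 21 d. The HSPE1 feature lies 24 places from a feature that rose by 1.46 at 7 d. Falls also stand beside features that fell more. The HTT feature lies 1 place from the MIF feature, and at 6 h they fell by 0.43 and 0.44, so these may not be separate falls. The QDPR feature lies 1 place from feature 5408, which fell by 0.75 at 7 d and by 0.58 at 21 d. The CKM feature lies 384 places from feature 5456, which fell by 0.53 at 6 h and by 0.59 at 7 d, and the TPT1 feature lies 1 place from feature 5772, which fell by 0.58 at 7 d.

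**Figure D4:**
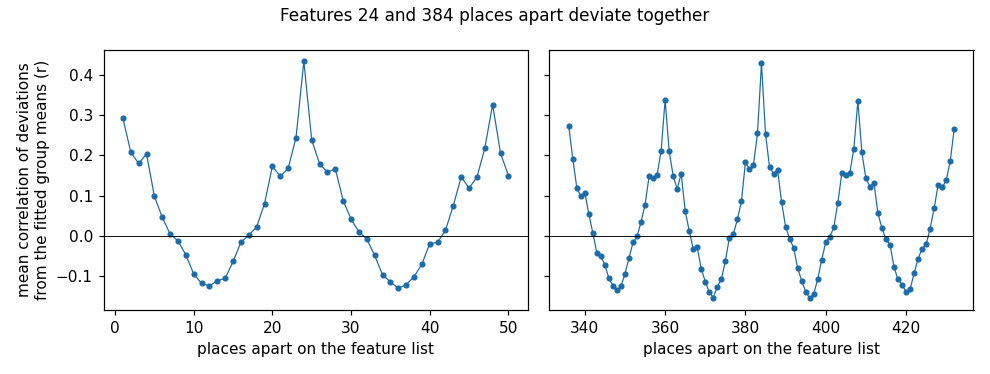
Mean correlation of deviations from the fitted group means between features (vertical axis) against how many places apart they stand on the feature list (horizontal axis). It is highest at distances of 24 (0.434) and 384 (0.430).

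The values within an array spread less widely in lesions than in controls. The paired difference in array SD was -0.257 at 6 h (lower in 8 of 10 animals), -0.171 at 2 d (8 of 10), -0.337 at 7 d (7 of 9) and -0.375 at 21 d (8 of 9). The exact two-sided sign-flip permutation p was 0.0195, 0.0371, 0.0234 and 0.0352, and 0.0371 for each after adjustment over the 4 ages. When array SD entered the model, 71 of the 210 calls at 6 h, 8 of 10 at 2 d, 153 of 393 at 7 d and 69 of 177 at 21 d were kept in the same direction. Among the calls kept were 57 rises and 14 falls at 6 h, 118 and 35 at 7 d, and 61 and 8 at 21 d. Array SD differs between the groups, so this covariate can also take up differences between lesion and control.

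**Figure D5:**
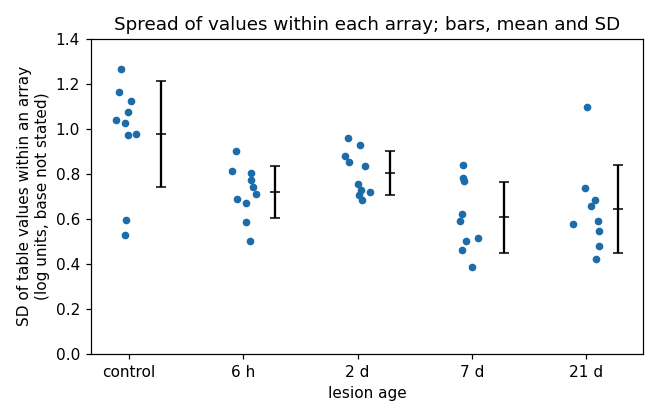
SD of the table values within each array (log units), by group, with each animal as a point and bars for the mean and SD. Controls average 0.976 and lesions of 7 d average 0.607.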

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

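The test of signal reaching neighbouring spots, and the test of scaling for the 2 d lesions, were chosen only after the result was seen.

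Dixon's test marked 22 values, out of 100 groups of values examined, as far from the rest of their group, where chance marks about 1 in 20 groups. Of the 22, 7 lie on the 6 h array of pig F. The values follow with the nearest other value of the same group. The correlation of an array with its own group was 0.237 for the 6 h lesion of pig F (nearest 0.832) and 0.847 for the 7 d lesion of pig G (0.909). The array SD was 1.10 for the 21 d lesion of pig C (0.736).

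On the 6 h array of pig F the feature listed as MYH7 had 1.94 (nearest 1.22), MAPK12 0.17 (2.04), TPI1 0.43 (1.58), UGP2 -0.50 (0.45), HSPE1 0.38 (2.35) and CAPNS1 3.91 (2.48). In pig D, XIRP2 had 0.36 in the control (nearest 0.05), MYH7 1.19 at 2 d (0.94), MIF 0.56 at 6 h (0.08), QDPR 0.81 at 2 d (1.07) and ANPEP 0.92 at 2 d (0.49). In pig E, XIRP2 had 0.64 at 2 d (nearest 0.21), TPM2 1.37 at 7 d (0.66), QDPR 0.74 in the control (1.16) and HSPE1 2.51 in the control (2.16). In pig J at 21 d, MYH7 had 1.54 (nearest 1.14) and NPPA 0.82 (0.39). TPI1 had 2.56 in the 21 d lesion of pig K (nearest 2.06), and CAPNS1 had 0.15 in the 7 d lesion of pig G (1.47).

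Lesion ages differed from each other by the direct limma test for 11 differences of named features. Between 6 h and 2 d these were 0.39 for TPM2, -1.08 for XIRP2 and -0.41 for JAK1. Between 2 d and 7 d they were 1.99 for XIRP2, 0.55 for JAK1, 0.45 for ANPEP, 0.38 for RACK1, -0.65 for CAPNS1, -0.41 for POMGNT1, -0.36 for TPT1 and -0.31 for COX7A1.

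Features close together on the spotting grid deviated together, with a correlation of 0.434 at 24 places apart. Position on the membrane stays open as a source. Neighbours inside a row correlated at 0.305 (1132 pairs) against -0.0352 across the end of a row (43 pairs). The difference was 0.340, with a bootstrap SE of 0.0379. The bootstrap drew pairs as if independent, while features deviate together, so this SE may be too small. When the local trend was subtracted, 75.3% of the 7 d calls were kept, and 72.9%, 70% and 70.6% at 6 h, 2 d and 21 d. The trend that was subtracted thus did not make most of these calls. It did move the balance of directions. At 6 h 91 higher and 119 lower became 129 and 104, at 7 d 178 and 215 became 222 and 177, and at 21 d 91 and 86 became 108 and 65. Whether the subtraction removed the correlation of neighbours was not checked, so local trends left after it are not excluded. Signal from a strongly rising spot may reach its neighbours. The 52 neighbours of 17 features that rose by over 1 at 21 d differed by 0.105 on average, against -0.0131 for random features (one-sided permutation p = 2e-04, 1 of 10000 draws as high). The random features were drawn singly, while neighbours deviate together, so this test cannot tell such signal from an effect of position. The rise listed as ANPEP is beside such a spot, as is that of the MYOZ1 feature beside XIRP2, and no biological explanation was tested.

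Lesions of 2 d lay nearer to control than lesions of 6 h, with 10 called features against 210. A linear trend over the array number is argued against as a cause, since with that number in the model the 2 d count was 3.86% of the 6 h count. Steps between runs of arrays were not modelled and stay open. Scaling between arrays is argued against, since the highest share under the other scalings tested or with array SD in the model was 8.65%, and a single animal is argued against, since the highest share without 1 animal was 6.99%. An exchange of labels between ages was not tested and stays open, as does the age of the lesion, the difference the design names.

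Values spread less widely within lesion arrays than within control arrays, by -0.337 at 7 d. A linear trend over the array number is argued against as a cause, since 99% of the 7 d difference was kept with that number in the model. Steps between runs of arrays were not modelled here either. A single stretch of the scale for all features, as from a change in labelling or exposure, cannot be told apart from a change in the tissue. It would leave the shape of an array's distribution as it was, and for the ratio of its range above the median to that below, the smallest adjusted exact paired permutation p over the 4 ages was 0.727, which does not show that the shape stayed the same.

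The counts were compared with 100 splits of the same samples, the real one included. The lowest share these splits can give is 1 of 100. By free splits, which do not keep the animal block, chance is argued against for the 210 called features at 6 h (1 of 100 splits had as many, highest other 112), the 10 at 2 d (1, highest other 3), the 393 at 7 d (1, highest other 0) and the 177 at 21 d (1, highest other 2). Within animals, 2 of 100 splits had as many at 21 d, with a highest of 224, as given below. By free splits chance is also argued against for the 88 features between 6 h and 2 d (1, highest other 12), the 235 between 2 d and 7 d (1, highest other 19) and the 342 at any age (1, highest other 89). For the 5 between 7 d and 21 d the kinds of split differ in outcome. By free splits chance cannot be excluded, since 5 of 100 had as many. The highest other free split there had 148, far above the real count, and the reason was not tested. By splits within animals, which keep the block of the design, chance is argued against for these 5 (1 of 100 had as many, highest other 1).

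Splits that only exchange labels within animals gave at most 88 called features at 6 h, 5 at 2 d, 73 at 7 d, 35 between 6 h and 2 d, 201 between 2 d and 7 d, 1 between 7 d and 21 d and 299 at any age, all below the real counts. At 21 d 2 of 100 such splits had as many as the real 177, and the highest, 224, exchanged pig C alone. Pig C had an array SD of 0.528 in the control and 1.10 at 21 d, opposite to the other 8 pigs, and 68.9% of the 21 d calls had their sign in pig C, against 87.6% to 98.3% in the others. A narrow control is not particular to pig C, since that of pig L had an array SD of 0.594, and pig L has no lesion of 21 d listed. XIRP2 was higher at 21 d than in the control in 9 of 9 pigs, pig C included, so a plain exchange of its samples is not shown.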

How the results depend on the processing

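Arrays scaled to equal mean and SD, the treatments that leave out the 6 h array of pig F or handle the copied column, the local trend and array SD in the model were chosen after seeing the data. XIRP2, JAK1, ANPEP and POMGNT1 against control at the ages where they were called, TPM2 at 6 h, and QDPR and CKM at 7 d kept their direction and call under all 28 alternatives, though QDPR at 7 d shrank to -0.24 with the local trend subtracted. Of 3805 values of named features and lists under alternatives, 3526 kept their side of the threshold, and those called among them kept their direction. Of the others 167 were no longer past the threshold, 107 came past it and 5 reversed while called in the main fit or the alternative. Changes of sign in values called in neither fit were not counted as reversed. The counts at 6 h, 2 d, 7 d and 21 d stayed within 1.5 times under 22, 24, 24 and 22 of 28 alternatives, those of the 3 steps in order of age under 25, 24 and 17, and the count at any age under 23 of 27.

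In the order 6 h, 2 d, 7 d, 21 d, 2 d against 6 h, 7 d against 2 d, 21 d against 7 d and any age, table values without quantile normalization gave 535, 23, 7.1e+02, 683, 37, 89, 0 (limma, 14 at an unadjusted p below 0.05) and 6.0e+02 (2 of these counts are rounded). Arrays centred on the median gave 542, 32, 747, 7.1e+02, 40, 117, 1 and 638. Array weights gave 603, 55, 662, 389, 316, 470, 18 and 709, with MAPK12 at 6 h at -0.20 and NPPA at 21 d at 0.23. Without muscle samples that have only 1 part CAPNS1 at 7 d was at -0.47. These 3 stayed called. On table values HSPE1 at 7 d reversed to -0.41, MYH7 at 7 d to -0.0073 and MYH7 at 21 d to -0.072. On median-centred values HSPE1 at 7 d reversed to -0.39 and MYH7 at 21 d to -0.048. Several called falls were larger on table values, such as CKM at 7 d (-1.33) and TPI1 at 7 d (-1.26). The cause of these larger falls was not tested gene by gene. With arrays scaled to equal mean and SD, 164, 252 and 167 features were lower at 6 h, 7 d and 21 d. On table values 426, 478 and 515 were lower. Without the 6 h array of pig F, genes gained at 7 d and 21 d had nearly the same differences as with it. HSPE1 at 21 d was at 0.32 both ways (adjusted p by limma 0.236 with it and 0.0126 without). That array is in neither group compared and enters through the shared fit and scaling. Across all scalings the median difference over features stayed under 0.1 in size. The mean difference at 6 h, 2 d, 7 d and 21 d was -0.11, -0.08, -0.14 and -0.16 on table values and -0.10, -0.06, -0.12 and -0.13 on median-centred values.

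With array SD in the model the counts were 104 at 6 h, 198 at 7 d, 97 at 21 d and 207 at any age. The median share of a called difference kept was 82.8% at 6 h, 96.6% at 2 d, 81.5% at 7 d and 81.9% at 21 d, while standard errors grew by a factor of 1.13, 1.05, 1.23 and 1.22, so calls ended through both. With only the groups compared in the fit, which holds fewer samples, the count was 124 at 6 h and 22 at 2 d. Subtracting the local trend ended the calls of MAPK12, MIF, TPI1, QDPR and CKM at 6 h, TPM2, TPT1, TPI1 and TUBA1B at 7 d, QDPR, UGP2 and CKM at 21 d (CKM -0.19, adjusted p = 0.15), TPM2 and JAK1 at 2 d against 6 h, and CAPNS1 and TPT1 at 7 d against 2 d. The first column only gave 111 at 6 h, by construction with the copied column of pig J. With that sample and the control of pig I left out the counts were 144 at 6 h and 121 at 21 d, and MIF, TPI1 and QDPR at 6 h, NPPA and UGP2 at 21 d, JAK1 at 2 d against 6 h, and CAPNS1 and COX7A1 at 7 d against 2 d were not called. Without the 6 h array of pig F the counts were 281 at 21 d, 314 for 7 d against 2 d and 13 for 21 d against 7 d.

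Without the animal block the counts were 215, 8, 405, 198, 89, 248, 4 and 372, and with the animal as a random block 196, 7, 396, 185, 84, 242, 4 and 357, so the pairing of samples changed no count by over 1.5 times. Some named calls did depend on the fixed block. TPI1 at 6 h was not called without the block (adjusted p = 0.0641) or with the random block (0.0746), nor was TPM2 at 2 d against 6 h (0.0544 and 0.067), and JAK1 at 2 d against 6 h was not called with the random block (0.0535). Leaving out each animal gave 143 to 239 at 6 h, 7 to 11 at 2 d, 282 to 416 at 7 d, 110 to 217 at 21 d, 60 to 101 for 2 d against 6 h, 143 to 276 for 7 d against 2 d, 1 to 9 for 21 d against 7 d and 235 to 372 at any age. The lowest were without pig K at 6 h, E at 7 d, I at 21 d and E for 7 d against 2 d. The list of shared sarcomere and Z disc genes passed at 6 h, 7 d and 21 d without pig D (adjusted p = 0.0426). Normexp background correction was not run, since it needs linear values and the table holds log values. Signal over background cannot be judged from these values, and the 25% dimmest features left out gave 234, 10, 381, 169, 89, 237, 5 and 338.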

Other observations

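The search through orders of the feature list and the fit with array SD were chosen only after the result was seen. Features without a gene symbol also changed, and the ones given here were chosen by small p-values after their values were seen. Feature 5139 stood at 0.98 ± 0.095 (SD, n = 10) in controls and rose by 1.19 at 6 h (SE 0.143, adjusted p = 1.722e-07), by 2.45 at 7 d (SE 0.148, adjusted p = 2.868e-16) and by 2.76 at 21 d (SE 0.148, adjusted p = 4.298e-18) by limma. At 2 d it differed by 0.09 (adjusted p = 0.868). The feature listed as XIRP2 was likewise called at 6 h, 7 d and 21 d and not at 2 d. Feature 5748 fell by 0.49 at 6 h (adjusted p = 0.000214), by 0.62 at 7 d (adjusted p = 2.398e-06) and by 0.49 at 21 d (adjusted p = 0.000183), with a difference of -0.10 at 2 d (adjusted p = 0.804). Feature 5438 fell by 0.61 at 7 d (adjusted p = 2.398e-06) and by 0.28 at 21 d (adjusted p = 0.0352).

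Because features with the same symbol were not shown to move together, 53681 structured orders of the list (shifts, reversals, exchanges of rows and columns, and orders within blocks of 384) were tried. As listed, the mean correlation within a symbol was 0.0194, and in the best order it was 0.213. With symbols permuted in that order it was 0.0632 on average, and the highest of 1000 permutations was 0.148. In that order 35.3% of the features of abundant muscle genes had values, against 41.4% of all features, so these genes were not found more often. The best order was picked from many, and none was used.

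With array SD in the model, 379 features followed the SD of their array beyond group and animal.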
